A study of Mus musculus with 20 samples.

How the data were processed

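Gene expression was measured in mouse tissues on short-oligonucleotide arrays of 12488 probe sets, 1 sample per array, on 20 arrays. Of these, 8 held subcutaneous adipose tissue and 12 held brain, heart, lung and skeletal muscle. The deposited values are intensity values on a linear scale, 1 per probe set and array. The method that summarised probes into a probe set value is not given in the sources used here. The mean intensity without the lowest and highest 2% of probe sets lay near 800 on 19 of the arrays, as a global scaling by the authors would leave it, and over 3 times as high on the brain hypoxia array. Values at or below 0 made up 17.5% to 21.2% of each adipose array and did not occur in the other tissues. For arrays, no count of molecules lies behind a value, and the number of arrays per group limits the precision.

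Of the probe sets, 66 are controls of the platform and were left out of every test. Of the remaining 12422, the reference annotation gives 1 gene symbol to 10833, several to 396 and none to 1193. Those with several or no symbols were counted but not named. A gene with several probe sets was represented by the one with the highest mean.

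The 8 adipose arrays form 4 groups of 2 arrays, by the words Con or Glucose and Hyp or NonHyp in their titles. The labels name 12-week-old C57BL-6J mice and C57BL-6J-Lep mice, which carry a mutation of the leptin gene, but do not say which array came from which strain, nor what Con and Glucose stand for. The titles also carry s2 or s4, with 1 array of each in every group. The 2 arrays of a group bear the letters a and b, which were read as replicates and are called numbers 1 and 2 here. The meaning of these codes is not given in the sources used here. The other 12 arrays hold 1 array for each of 4 tissues under 3 conditions (control, sleep fragmentation, hypoxia), from 20-week-old C57BL-6J mice. The labels do not say whether replicate arrays came from separate animals, so the p-value of a gene here measures only the spread between arrays.

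Values were taken to log2 with an offset of 97.7, the percentile 20 of all positive values pooled. On the adipose arrays, where values at or below 0 occur, values under the offset were set to it, so that 6.61 is the lowest log2 level there, called the floor below. A fold against a group with every array at the floor is a lower bound if no array of the other group lies there, and is written "at least". On the same condition, where some arrays of the lower group lie at the floor, the difference is a lower bound in size as well. In the other tissues the offset was added to each value. The trimmed means of the adipose arrays lay within 5% of each other, and their deposited scaling was kept. The 12 arrays of the tissue panel were quantile normalized together. Each fit kept the probe sets whose mean (for the panel, whose highest tissue mean) lay above the 40th percentile, 7453 in either fit.

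Each comparison was tested with limma 3.58.1 under R 4.3.3 (lmFit and eBayes, two-sided), at a Benjamini-Hochberg adjusted p of 0.05 over all probe sets tested. The adipose fit had 4 group means and 4 residual degrees of freedom. Its contrasts were Glucose minus Con, hypoxia minus non-hypoxia on average and within each of Con and Glucose, and the difference between those hypoxia effects. The panel fit had tissue and condition as terms and 6 residual degrees of freedom, so it tests changes shared by the tissues. Each tissue was also compared with the mean of the other 3. Differences within a tissue have no replicates and no test, and probe sets 2-fold or more apart were counted there. The error given beside a log2 difference is the standard error of the fit.

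Lists of genes, 37 in number, covering metabolic pathways, stress and signalling responses and cell types, were tested with limma's camera at a preset correlation between genes of 0.01, where at least 5 of their genes were measured, with adjustment over the lists of a contrast. Camera sets the genes of a list against all other genes. At the preset correlation its p-value therefore rests mainly on the spread between genes and not on that between arrays. Camera with an estimated correlation and fry were run beside it. Within a tissue, the median of a list was placed among 10000 random lists of like size and expression. The fits, the contrasts, the filter, the lists and the rule for named genes were chosen before the data were examined. That rule names, in each contrast, up to 10 genes highest and 10 lowest by log2 difference among those past the threshold with no overlap between the groups (in the panel, the same sign in all 4 tissues). Where a direction has fewer than 5, the 5 with the smallest unadjusted p are named. Up to 4 members of a list are named, as are the 4 highest and lowest probe sets within a tissue and the 3 highest per tissue identity. Lep, Adipoq, Vegfa and Slc2a1 are given in adipose tissue, and Vegfa and Slc2a1 in the panel, whatever their values.

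The fits were tested on simulated data with 7453 probe sets and 10 runs, in which the arrays varied independently. In the Glucose minus Con contrast, 74.2% of true 4-fold changes and 5.97% of true 2-fold changes were found, and 8.29% of the calls were false. For average hypoxia 73.2% of 4-fold and 5.52% of 2-fold changes were found. There 4.97% of unchanged probe sets had an unadjusted p under 0.05 in limma, against 110 of 7453 probe sets on the real arrays. After removing group means, same-numbered real arrays correlated at 0.181 within Con and 0.415 within Glucose. The shares found may therefore not describe the real adipose contrasts. For hypoxia within Con, 0.909% of 4-fold changes were found, and for the difference of the hypoxia effects 0%. In the panel, 74.9% of 2-fold changes shared by the tissues were found for hypoxia minus control.

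The alternatives tried were quantile normalization of the adipose arrays, the deposited scaling or a rescaling of the panel, an offset 4 times smaller and 4 times larger, no filter and a filter at the 60th percentile, the replicate number or the s code as a term, eBayes with trend and robust options, array weights, the mean of a gene's probe sets, fits of only the arrays compared, quantile normalization within each tissue, each replicate or tissue left out, and arrays chosen after seeing the data left out. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15. No array was left out of the reported values.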

Results

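The series addresses sleep apnea and glucose metabolism in mice. Subcutaneous adipose tissue was profiled on 8 arrays, in 4 groups of 2: Con with hypoxia, Con without, Glucose with hypoxia and Glucose without. Intermittent hypoxia, a laboratory model of the oxygen swings of sleep apnea, was given for 16 hours a day over 5 days, and the other mice breathed room air. Brain, heart, lung and skeletal muscle of other mice were profiled on 12 arrays, 1 per tissue for control, sleep fragmentation (repeated interruption of sleep) and hypoxia. On the adipose arrays 17.5% to 21.2% of values lay at or below 0, and on the others none did. The median intensity per array ran from 265 to 411, except on the brain hypoxia array, with 1475. The ratio of the 3' to the 5' control probe sets of Gapdh ran from 0.802 to 1.02 on the adipose arrays, and that of Actb from 0.756 to 1.70. In the panel, the Actb ratio was 0.0343 on the brain hypoxia array and 0.0288, 0.0635 and 0.0351 on the lung control, fragmentation and hypoxia arrays. The Gapdh ratio was 0.0261, 0.264 and 0.00899 on the muscle control, fragmentation and hypoxia arrays, and 0.443, 1.15 and 0.136 on those of heart.

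The comparison of Glucose with Con asks how the adipose transcriptome differed between the arrays so titled. Genes of lymphocytes were far lower on the 4 Glucose arrays than on the 4 Con arrays. Igkv6-23, an immunoglobulin light chain gene segment, differed by -5.81 ± 0.35 log2 (56.3-fold lower), Cd79a, a chain of the B cell receptor, by -4.16 ± 0.27 (17.9-fold), and Ccl5, a chemokine made by T cells, by -4.42 ± 0.28 (21.4-fold). H2-Ab1, a class II histocompatibility chain, was 17.1-fold lower, H2-DMa, which loads peptides onto class II molecules, 14.6-fold, and Coro1a, an actin-binding protein of leukocytes, 16.1-fold. Cidea, a lipid droplet protein abundant in brown fat, was 50.1-fold lower (-5.65 ± 1.04), Tnnt1, the troponin T of slow muscle fibres, 23.3-fold (-4.54 ± 0.75), and the urinary pheromone carriers Mup5 and Mup3 were 18.2-fold and 11.3-fold lower. In the other direction Mest, an imprinted gene that rises with fat expansion, was 18.1-fold higher on Glucose (4.18 ± 0.29, with a mean log2 level of 12.92 against 8.74).

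Among the other genes higher on Glucose were Hpgd, which inactivates prostaglandins (3.37 ± 0.25, 10.3-fold), Fmr1, an RNA-binding protein (3.23 ± 0.26, 9.41-fold), Cdr2 (3.13 ± 0.21), and Maoa, which oxidises monoamines (3.09 ± 0.30). Sc5d, a late enzyme of cholesterol synthesis, was 8.47-fold higher (3.08 ± 0.30), Npr3, the clearance receptor of natriuretic peptides, 7.92-fold, and Map6, a microtubule protein, 7.33-fold. D430019H16Rik and Pigs, a subunit of the enzyme that attaches lipid anchors, differed by 3.06 ± 0.40 and 2.98 ± 0.50. Each of these genes had adjusted p between 0.00053 and 0.0195 by limma, with all 4 arrays of one side beyond all 4 of the other. Igkv6-23, Cidea, Tnnt1, Ccl5, Cd79a, H2-Ab1, Coro1a, H2-DMa and Mup3 were at the floor on 1 to 3 of the 4 Glucose arrays, and Sc5d, D430019H16Rik, Pigs and Map6 on 1 to 3 of the 4 Con arrays, so these folds are lower bounds. Some genes were at the floor on every array of one side: Ltb, a lymphotoxin chain, was at least 19.8-fold lower on Glucose, Glycam1, a ligand made by lymph node vessels, at least 14.2-fold, and Folh1, a folate hydrolase, at least 8.94-fold higher. These were singled out after their values were seen. Of the genes fixed in advance none passed: Vegfa, an angiogenic factor, differed by -1.07 ± 0.40 (adjusted p = 0.158), Slc2a1, a glucose transporter, by -0.34 ± 0.61 (0.794), Adipoq, the hormone adiponectin, by -0.57 ± 0.39 (0.433), and Lep, the hormone leptin, by -0.42 ± 0.83 (0.81), with another probe set of Lep of opposite sign.

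**Figure D1:**
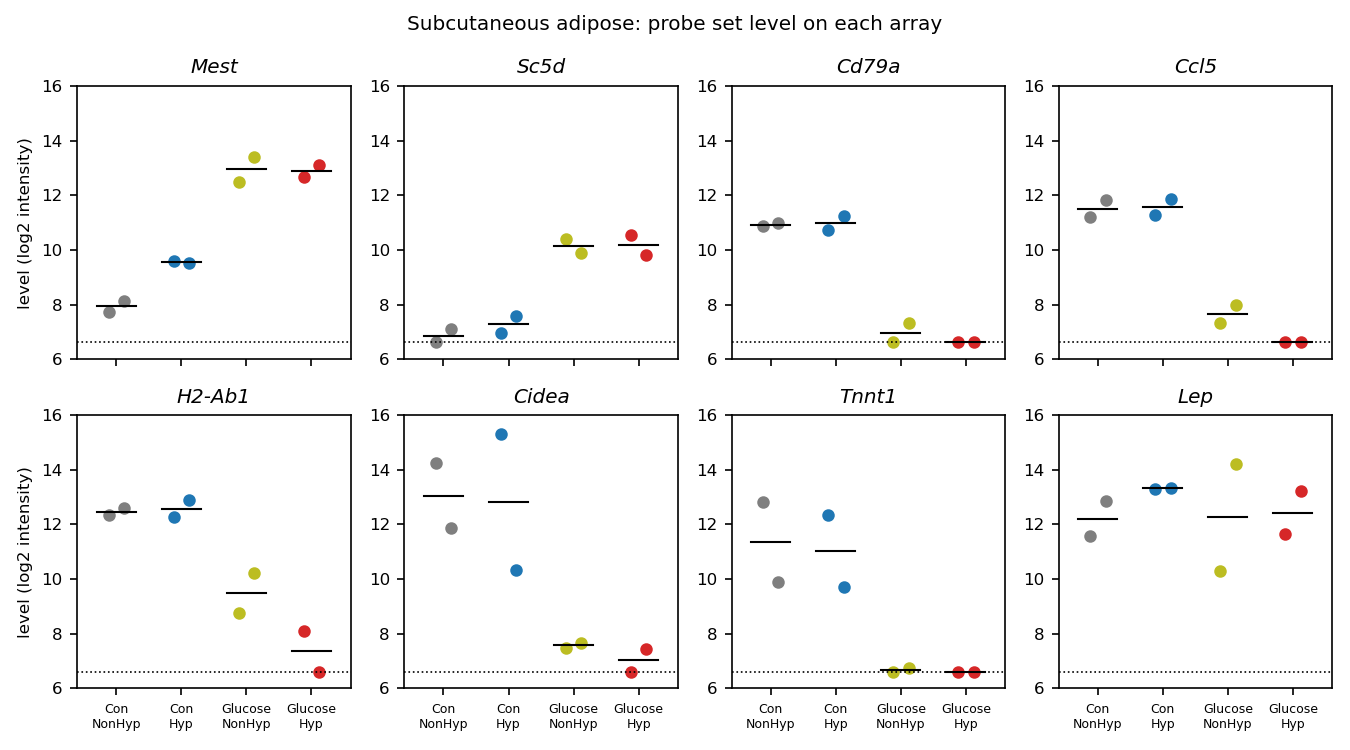
Log2 level of Mest, Sc5d, Cd79a, Ccl5, H2-Ab1, Cidea, Tnnt1 and Lep on each of the 8 adipose arrays, as points by group, with a line at the mean of the 2 arrays and a dotted line at the floor of 6.61. Mest and Sc5d lie higher on all Glucose arrays, and the Con arrays numbered 1 carry the highest Cidea, 15.32 with hypoxia and 14.26 without.

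Over all probe sets, 565 of 7453 passed in limma, 301 higher and 264 lower on Glucose, and 1789 had an unadjusted p under 0.05. The 2 sides did not overlap for 19.8% of all probe sets tested, where chance gives 2.86% if the arrays vary independently. They may not, since same-numbered arrays with and without hypoxia correlated at 0.877 to 0.923 and arrays of the same group at 0.843 to 0.896. Within the s4 arrays 142 passed, 54 higher and 88 lower, and within the s2 arrays 0 passed in limma, with 1189 at an unadjusted p under 0.05. The count fell to 344 without the Con hypoxia array numbered 1, 362 without number 2, 361 and 347 without the Con non-hypoxia arrays numbered 1 and 2, 240 and 267 without the Glucose hypoxia arrays numbered 1 and 2 (39.2% and 41.9% of them higher on Glucose), and 325 without the Glucose non-hypoxia array numbered 1. Without both Con arrays numbered 1, which leaves 1 array in each Con group, the count fell further. Sc5d, H2-Ab1, Map6, Mup3, Mup5, D430019H16Rik and Pigs no longer passed there. Their log2 differences in that fit were 2.80, -4.31, 2.84, -3.72, -4.59, 3.01 and 2.51. No named gene passed within s2, and Hpgd (0.0519), Maoa (0.0519), Npr3 (0.0593), Mup3 (0.084) and Cidea (0.0539) did not within s4. Cidea no longer passed without the Con non-hypoxia array numbered 1 (adjusted p = 0.069), either Glucose hypoxia array (0.0779 and 0.0581) or the Glucose non-hypoxia array numbered 1 (0.0592). Tnnt1 was lost without either Glucose hypoxia array (0.0519 and 0.0501), and Pigs without the Con hypoxia (0.0597), Con non-hypoxia (0.0523) or Glucose hypoxia (0.0567) array numbered 1.

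B cell genes were lower on Glucose as a group. All 8 measured members had negative differences and 6 fell (6 adjusted over the list alone), among them Cd79a, its partner Cd79b (-3.01 ± 0.31), Fcer2a, a receptor for immunoglobulin E (-2.33 ± 0.42), and Ms4a1, the surface protein CD20 (-2.31 ± 0.27), and the list's camera adjusted p was 2.11e-07 (adjusted p = 0.184 with an estimated correlation). Of 6 T cell genes 5 were lower and 3 fell (4 adjusted over the list alone): Thy1, a surface glycoprotein (-2.99 ± 0.55), Cd8b1, a chain of the CD8 coreceptor (at least 6.22-fold), and Cd2, an adhesion receptor (-1.43 ± 0.34), with adjusted p = 0.000749 for the list (adjusted p = 0.184 with an estimated correlation). Of 16 interferon response genes 15 were lower and 4 fell (7 adjusted over the list alone). These were the immunoproteasome subunits Psmb9 (-2.69 ± 0.25) and Psmb8 (-1.48 ± 0.30), the peptide transporter Tap1 (-1.22 ± 0.26) and Ifit3 (-1.04 ± 0.24), with adjusted p = 2.04e-06 for the list (adjusted p = 0.184 with an estimated correlation). Cholesterol synthesis genes were higher in 11 of 12 cases and 5 rose (9 rose and 1 fell adjusted over the list alone). They included Sc5d, Msmo1 (2.28 ± 0.26), Hmgcs1, an early enzyme of the pathway (1.72 ± 0.29), and Lss, which closes the sterol rings (1.36 ± 0.27), and the list's adjusted p was 2.73e-05 (adjusted p = 0.208 with an estimated correlation). These 4 lists passed with any 1 array left out and without both Con arrays numbered 1, and fry gave 0.00325 for each.

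Genes of the respiratory chain were lower on Glucose in 47 of 49 cases, with a median of -0.98 and a list adjusted p of 1.65e-10 (adjusted p = 0.879 with an estimated correlation). Of these, 2 fell (0 adjusted over the list alone), namely Cox7b, a subunit of cytochrome oxidase (-2.28 ± 0.55), and Ndufa6, a subunit of complex I (-1.60 ± 0.36). Brown adipocyte genes were lower in 5 of 5 cases (median -2.92, 1 fell, Cidea, and 2 adjusted over the list alone, adjusted p = 0.0064; adjusted p = 0.879 with an estimated correlation). Fatty acid oxidation genes were lower in 18 of 19 cases (adjusted p = 0.00293, Eci1 -2.13 ± 0.48 fell, 0 adjusted over the list alone), as were tricarboxylic acid cycle genes in 16 of 18 (adjusted p = 0.00206, 0 fell in limma at adjusted p, Sdhb -1.61 ± 0.44). With an estimated correlation both of these lists had adjusted p = 0.879 as well. The brown adipocyte genes stood apart on the Con arrays numbered 1, at medians of 3.80 (hypoxia) and 3.66 (non-hypoxia) above the mean of the 8 arrays, against -1.25 and 0.83 on those numbered 2. The respiratory chain genes on the same arrays stood at 1.24 and 0.88 against -0.23 and 0.19. Unlike the other lists of this paragraph, the respiratory chain list was not lost when any of these arrays was left out. Without both Con arrays numbered 1 the list adjusted p was 0.16 for brown adipocyte genes, 0.867 for fatty acid oxidation and 0.716 for the tricarboxylic acid cycle. Leaving out the Con non-hypoxia array numbered 1 alone gave 0.0561, 0.0938 and 0.0582, and leaving out the Con hypoxia array numbered 1 gave 0.123 for fatty acid oxidation and 0.104 for the tricarboxylic acid cycle.

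Skeletal muscle fibre genes were lower on Glucose in 20 of 20 cases (median -0.74), with a list adjusted p of 0.0044 (adjusted p = 0.879 with an estimated correlation). Tnnt1 and Myh7, the slow myosin heavy chain (at least 12.2-fold), fell (2 adjusted over the list alone). The medians of this list ranged between arrays from -2.80 (Glucose non-hypoxia number 1) to 1.80 (Con non-hypoxia number 2). They lay apart within a group too, with 0.94 on the Glucose non-hypoxia array numbered 2. How much muscle tissue each adipose sample held is not given, so the differences of this list cannot be read as changes in fat. The list's adjusted p was 0.908 without the Glucose non-hypoxia array numbered 1, 0.0697 without the Con hypoxia array numbered 1 and 0.0553 without the Glucose hypoxia array numbered 1, and 0.16 without both Con arrays numbered 1. Of the 26 hypoxia response genes outside glycolysis, 2 rose (4 adjusted over the list alone): Vhl, which marks hypoxia-inducible factors for destruction (at least 4.69-fold), and Lox, which crosslinks collagen (2.17). That share is near the one over all probe sets (565 of 7453), and the list did not pass. Of the 18 inflammation genes 3 rose and 2 fell (6 and 4 adjusted over the list alone), among them Saa3, an acute phase protein (2.67 ± 0.29), Il1r2, a decoy interleukin 1 receptor (-2.35), and Vcam1, an adhesion molecule (-1.67). The inflammation list did not pass either. None of 9 adipocyte genes passed.

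**Figure D2:**
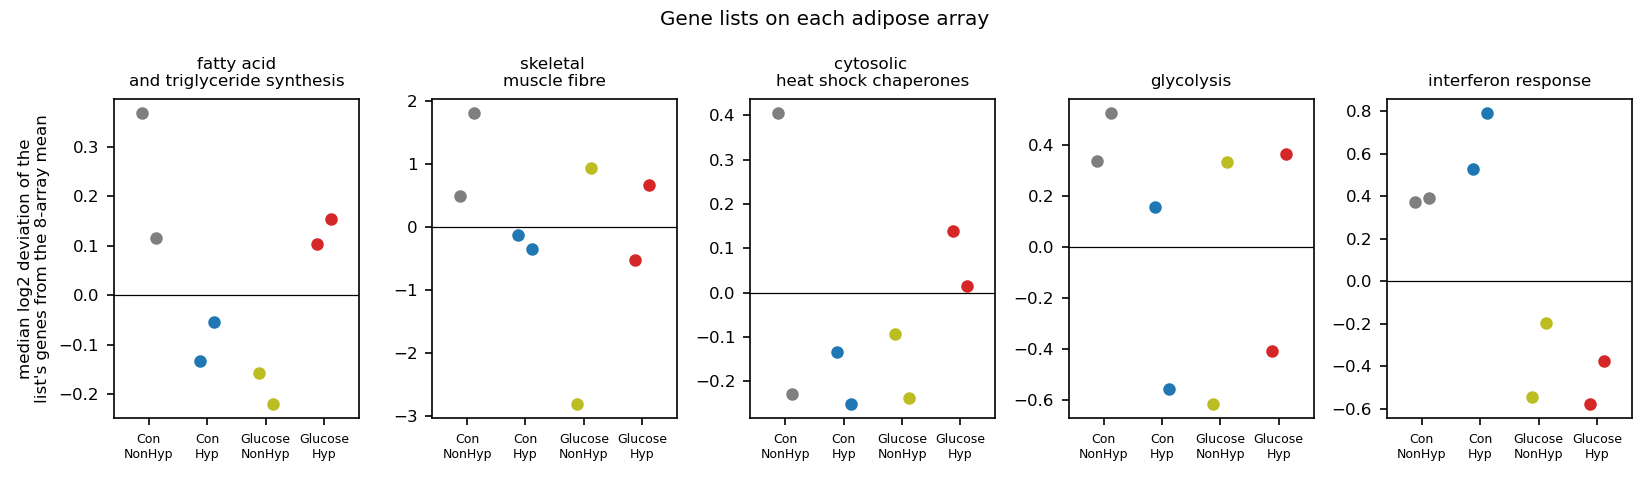
Median log2 deviation of a list's genes from their mean over the 8 adipose arrays, on each array, for fatty acid and triglyceride synthesis, skeletal muscle fibre, heat shock chaperones, glycolysis and interferon response. The skeletal muscle fibre list spans the widest range, -2.80 to 1.80.

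Hypoxia was compared with room air over Con and Glucose together, to ask what intermittent hypoxia changed in adipose tissue. No gene passed. The smallest unadjusted p belonged to Sprr2i, a cornified envelope protein of epithelia, at 2.44 ± 0.43 log2 higher on the 4 hypoxia arrays than on the 4 others, of which 3 were at the floor, to Igkv6-23 (1.41 ± 0.35), Cpne6, a calcium-dependent membrane protein (1.22), Tal2 (1.58, with 1 of the hypoxia arrays and all 4 others at the floor) and Mrps18a (1.11, with another probe set of opposite sign). On the lower side stood Myo7a, an unconventional myosin (-1.83 ± 0.36), Cbr2, a carbonyl reductase (-1.22), Ppy, pancreatic polypeptide (-1.28), Gata2, a transcription factor of blood and fat precursors (-1.21), and Cryl1 (-1.13). Myo7a, Cbr2 and Gata2 were at the floor on the Glucose hypoxia arrays, and Sprr2i, Igkv6-23 and Cpne6 on some non-hypoxia arrays. The differences of these genes are therefore lower bounds in size. Vegfa differed by 0.02 ± 0.40, Slc2a1 by 0.57 ± 0.61, Lep by 0.64 ± 0.83 and Adipoq by 0.09 ± 0.39. In limma 0 of 7453 probe sets passed, with 110 at an unadjusted p under 0.05, fewer than the 373 that chance gives. Within the s2 arrays 0 passed in limma with 222 at an unadjusted p under 0.05, and within s4 0 with 284. The list nearest to passing was cholesterol synthesis (adjusted p = 0.0561), and the hypoxia response list had 0.67.

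Within Con, hypoxia was compared with room air on 2 arrays each, and genes of muscle fibres and of lipid synthesis were lower as groups (adjusted p = 0.753 with an estimated correlation for both lists), though no single gene passed. Skeletal muscle fibre genes were lower in 20 of 20 cases (median -1.33, list adjusted p = 1.12e-05; adjusted p = 0.753 with an estimated correlation), with Pgam2, a muscle glycolytic enzyme, 8.02-fold lower (standard error 1.36 log2) and Casq1, a calcium store protein, at -2.60 ± 0.90. Glycolysis genes were lower in 11 of 14 cases (0.00402; Pfkm -1.82), heat shock chaperones in 13 of 17 (0.00402; Hspa1a -1.44, Bag3 -1.35), and fatty acid and triglyceride synthesis genes in 11 of 15 (0.0118; Elovl6, a fatty acid elongase, -1.41, Acly, which makes cytosolic acetyl-CoA, -0.83). With an estimated correlation the last 3 lists had adjusted p = 0.753 as well. Pgam2 and Eno3 belong to both the glycolysis and the muscle fibre list, so glycolysis is not independent of muscle fibre here. The muscle tissue held by each sample is not given. The muscle fibre result therefore cannot be read as a response to hypoxia. Extracellular matrix genes were lower in 22 of 30 cases (0.00402; Col1a1 -0.98, Fn1 -0.96; adjusted p = 0.905 with an estimated correlation). The Actb ratio of 3' to 5' control probe sets was 1.70 and 1.37 on the Con hypoxia arrays and 0.788 and 0.942 on the Con non-hypoxia arrays. Over all genes and adjusted over the list alone, 0 members of these lists passed in limma. The smallest unadjusted p belonged to Nnat, an imprinted membrane protein (1.85 ± 0.36), Cpne6 (2.29 or higher, with a non-hypoxia array at the floor), Tuft1 (1.66), Nnmt, which methylates nicotinamide (1.44), and Olfm1 (at least 2.94-fold) on the higher side. On the lower side it belonged to Ppy (-1.86, with another probe set of opposite sign), Smr2 (-1.65), 5031439G07Rik (-1.64), Sac3d1 (-1.38) and Bhlhe40, a clock and hypoxia regulator (-1.47). Vegfa differed by 0.29 ± 0.56, Slc2a1 by -0.15 ± 0.87, Lep by 1.10 ± 1.18 and Adipoq by 0.29 ± 0.55. In limma 0 probe sets passed, with 218 at an unadjusted p under 0.05.

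Each of these lists no longer passed with a certain array left out, and all but extracellular matrix kept their direction. Without the Con non-hypoxia array numbered 1 the adjusted p was 0.958 for heat shock chaperones, 0.191 for extracellular matrix, 0.325 for fatty acid and triglyceride synthesis and 0.195 for glycolysis. Without the Con hypoxia array numbered 2 it was 0.321 for heat shock chaperones, 0.12 for fatty acid and triglyceride synthesis, 0.461 for glycolysis and 0.0757 for skeletal muscle fibre. Extracellular matrix turned in direction without the Con hypoxia array numbered 1 (0.314). After quantile normalization fatty acid and triglyceride synthesis had 0.0628. The brown adipocyte medians of the Con hypoxia arrays, 3.80 and -1.25, lay further apart than those of the other 3 groups.

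Within Glucose, on 2 arrays each, lipid synthesis genes were higher with hypoxia as a group. Fatty acid and triglyceride synthesis genes were higher in 11 of 15 cases (median 0.40, list adjusted p = 0.000263; adjusted p = 0.291 with an estimated correlation), with the desaturase Scd2 at 1.31 ± 0.49, Elovl6 at 1.27, Acly at 1.18 ± 0.38 and Thrsp, a lipogenic regulator, at 1.18. Skeletal muscle fibre genes were higher in 17 of 20 cases (0.00621; Myh1 2.85, Tnnt3 2.28) and cholesterol synthesis genes in 11 of 12 (0.0139; Cyp51 0.82, Msmo1 0.81), and both had adjusted p = 0.973 with an estimated correlation. For the muscle fibre genes the muscle tissue held by each sample is again not given. Over all genes and adjusted over the list alone, 0 members of these lists passed in limma. The smallest unadjusted p belonged to Hoxc6, a homeobox factor (1.55), Igkv6-23 (2.22), Folr1, a folate receptor (1.62), Pklr, a pyruvate kinase (2.19), and Tal2 (at least 4.70-fold) on the higher side. Igkv6-23, Folr1 and Pklr each had a non-hypoxia array at the floor, so their differences are lower bounds. On the lower side it belonged to Gata2 (at least 4.30-fold), Cbr2 (at least 3.92-fold), Myo7a (at least 6.93-fold), Grk6, a receptor kinase (at least 7.68-fold), and Pla2g4a, a phospholipase (-1.40). Vegfa differed by -0.26 ± 0.56, Slc2a1 by 1.29 ± 0.87 (a lower bound, with a non-hypoxia array at the floor), Adipoq by -0.10 ± 0.55, and Lep by 0.17 ± 1.18, with another probe set of opposite sign. In limma 0 probe sets passed, with 159 at an unadjusted p under 0.05. Without the Glucose hypoxia array numbered 2 the adjusted p was 0.13 for fatty acid and triglyceride synthesis, 0.137 for cholesterol synthesis and 0.659 for skeletal muscle fibre. Without the Glucose non-hypoxia array numbered 1 skeletal muscle fibre turned in direction (0.00179) and cholesterol synthesis had 0.262, and without the Glucose hypoxia array numbered 1 cholesterol synthesis had 0.127.

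The hypoxia effect was then compared between Glucose and Con. The Actb ratio of 3' to 5' control probe sets differed along the same lines. It was 1.70 and 1.37 with hypoxia and 0.788 and 0.942 without in Con, and 0.810 and 0.775 with and 0.756 and 1.27 without in Glucose. Its part in the list results below was not tested. Lipid synthesis genes differed as a group: 13 of 15 fatty acid and triglyceride synthesis genes had a more positive hypoxia effect in Glucose (median 0.84, list adjusted p = 4.02e-05; adjusted p = 0.241 with an estimated correlation), with Elovl6 at 2.68 ± 1.20, Acly at 2.01 ± 0.53 and Scd2 at 1.49. This list passed with any 1 array left out (highest adjusted p 0.0128). Skeletal muscle fibre genes had a more positive effect in Glucose in 19 of 20 cases (median 2.27, 1.07e-06; Myh1 4.15, Ckm 3.70), as did glycolysis genes in 12 of 14 (0.00941; Pgam2 3.40, Pfkm 2.87) and heat shock chaperones in 12 of 17 (0.00778; Hsph1 1.63, Hspa1a 1.53). Pgam2 and Eno3 belong to both the glycolysis and the muscle fibre list. Both lists had their lowest median on the Glucose non-hypoxia array numbered 1 (-0.61 and -2.80), so glycolysis is not a separate finding. The muscle fibre median was 0.94 on the other Glucose non-hypoxia array. The muscle tissue held by each sample is not given, so this difference cannot be read as one in the response to hypoxia. Interferon response genes had a more negative effect in 15 of 16 cases (0.0231; Gbp3 -0.96, Psmb9 -0.88). With an estimated correlation these 4 lists had adjusted p = 0.988, and 0 members of the 5 lists passed in limma, over all genes or adjusted over the list alone.

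The genes with the smallest unadjusted p for this difference were Hoxc6 (2.45), Sac3d1 (2.44, with another probe set of opposite sign), Bysl (2.71), Atn1 (2.42) and Clgn (3.80) on the positive side. Grk6 (-5.05 or lower, with the Glucose hypoxia and the Con non-hypoxia arrays at the floor), Nnat (-2.18), Srsf4, a splicing factor (-2.30), Gstt2, a glutathione transferase (-3.05 or lower, with the Glucose hypoxia arrays at the floor), and Mcrs1 (-1.98) stood on the negative side. Vegfa differed by -0.54 ± 0.80, Slc2a1 by 1.45 ± 1.22, Lep by -0.93 ± 1.66 and Adipoq by -0.39 ± 0.78. In limma 0 probe sets passed, with 246 at an unadjusted p under 0.05. Skeletal muscle fibre was lost without the Glucose non-hypoxia array numbered 1 (0.215). Without the Con non-hypoxia array numbered 1 glycolysis had 0.209, heat shock chaperones 0.713 and interferon response 0.235, and without the Con hypoxia array numbered 2 they had 0.327, 0.141 and 0.118. Without the Glucose non-hypoxia array numbered 1 glycolysis had 0.448 and heat shock chaperones 0.0856, without the Glucose hypoxia array numbered 2 glycolysis had 0.0963, and interferon response had 0.292 without the Glucose hypoxia array numbered 1 and 0.207 without the Glucose non-hypoxia array numbered 2.

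Each tissue of the panel was compared with the other 3 to check the tissue labels. Genes of each tissue stood highest on its own 3 arrays. Snap25, a synaptic vesicle fusion protein, was 6.74 ± 0.25 log2 higher in brain, with Zic1, a neural transcription factor (6.09), and Pcsk1n (5.71). Ankrd1, a stress-responsive muscle protein (5.17), Myh6, the atrial myosin heavy chain (5.03), and Tnnt2, cardiac troponin T (4.82), were higher in heart. Napsa, a protease of alveolar cells (5.95 ± 0.11), Wfdc2 (5.90) and Krt19, a keratin (5.40), were higher in lung, and Myh1, a fast myosin (5.75 ± 0.82), Tnnt3, fast troponin T (5.55), and Ryr1, the calcium release channel (5.45), in skeletal muscle. In limma 3683 probe sets passed for brain (1753 higher), 2862 for heart (1422), 4604 for lung (2095) and 3901 for muscle (1853). The count for heart was 1713 without the fragmentation arrays and 1763 without the control arrays. Higher in their own tissue were 12 of 12 neuron genes, 8 of 8 oligodendrocyte genes, 7 of 8 astrocyte genes, 13 of 15 cardiomyocyte genes, 7 of 9 lung epithelium genes and 15 of 20 skeletal muscle fibre genes. Sftpc, the surfactant protein C, was lower in lung (-1.27, adjusted p = 0.0308) and Pvalb, a calcium buffer of fast fibres, was lower in muscle (-2.99, adjusted p = 0.00265).

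Sleep fragmentation was compared with control across the 4 tissues, to ask which genes moved with disturbed sleep in every tissue. Glucocorticoid response genes were higher as a group: 14 of 18 had positive differences (median 0.35, list adjusted p = 6.65e-07; adjusted p = 0.157 with an estimated correlation). Ddit4, an inhibitor of growth signalling, stood at 1.36 ± 0.39, Sult1a1, a sulfotransferase, at 0.95 ± 0.15, Fkbp5, a chaperone of the glucocorticoid receptor, at 0.78 ± 0.25 and Mt1, a metallothionein, at 0.76 ± 0.30. Of the members 0 passed over all genes in limma and 4 adjusted over the list alone. Within a tissue the list's median was 0.50 in heart and 0.64 in lung, each at the percentile 100 of random lists, 0.34 in muscle (99.86) and 0.11 in brain (90.37, 11 of 18 higher). The muscle fragmentation array also carried transcripts of adipocytes and epididymis, given below. The list passed with any 1 tissue left out (highest adjusted p 0.00506). Other genes with the smallest unadjusted p were Ttr, a carrier of thyroid hormone (0.91), Apod, a lipid carrier (0.81), Mup5 (1.32) and Smoc1 (1.20), and on the lower side Col15a1, a basement membrane collagen (-0.95 ± 0.18), Vamp3 (-0.61), Myt1 (-0.71), Lxn (-0.78) and Mrpl54 (-0.57). Vegfa differed by -0.21 ± 0.19 and Slc2a1 by 0.07 ± 0.23. In limma 0 probe sets passed, with 336 at an unadjusted p under 0.05 (smallest adjusted p 0.58).

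**Figure D3:**
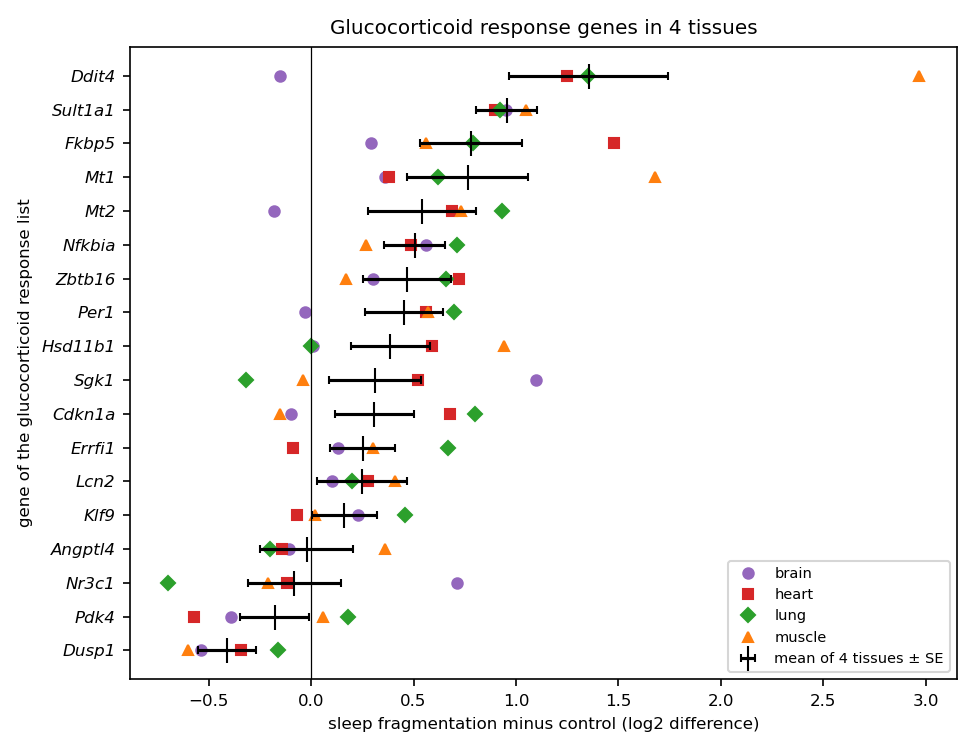
Log2 difference, fragmentation minus control, of the 18 glucocorticoid response genes in brain, heart, lung and muscle, as points, with the mean over the 4 tissues and its standard error. Ddit4 has the highest mean, 1.36.

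Hypoxia was compared with control across the same tissues. Both exposures were set against the same control arrays. A list or gene higher with both, as the glucocorticoid list and Apod were, is therefore not an independent finding in each. Immediate early genes were lower as a group, with 15 of 19 negative (list adjusted p = 0.0105; adjusted p = 0.265 with an estimated correlation). Zfp36, which destabilises inflammatory transcripts, stood at -0.87 ± 0.25 and Fos, a transcription factor induced by stimuli, at -0.84 ± 0.26. Glucocorticoid response genes were higher in 13 of 18 cases (0.0396; Ddit4 1.14, Fkbp5 0.83, Zbtb16 0.69, Sgk1 0.54; adjusted p = 0.609 with an estimated correlation). Cardiomyocyte genes were lower in 10 of 15 cases (0.0253; Nppa -0.93, Myl2 -0.83; adjusted p = 0.609 with an estimated correlation), and neuron genes higher in 10 of 12 (0.0396; Syt1 0.97; adjusted p = 0.683 with an estimated correlation). Over all genes and adjusted over the list alone, 0 members of these lists passed in limma. The smallest unadjusted p belonged to Apod (1.08 ± 0.21), Kifap3, a kinesin adaptor (0.75), Rufy3 (0.87), Fzd2, a Wnt receptor (0.92), and Nfyb (0.67), and on the lower side to Mob2 (-1.27), Rpl37a, a ribosomal protein (-1.05), Rcan1, a calcineurin inhibitor (-0.75), Ctnnd2 (-0.55) and Sprr2b (-0.95). Vegfa differed by 0.19 ± 0.19 and Slc2a1 by 0.25 ± 0.23. In limma 0 probe sets passed, with 371 at an unadjusted p under 0.05 (smallest adjusted p 0.908).

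The immediate early list passed with any 1 tissue left out (highest adjusted p 0.0306). The glucocorticoid list had 0.104 without brain, 0.232 without heart, 0.297 without lung and 0.336 without the brain hypoxia array. Cardiomyocyte had 0.477 without heart and 0.201 without muscle, and neuron 0.75 without muscle, 0.176 without the brain hypoxia array and 0.247 without the muscle control array. With the arrays rescaled to a common trimmed mean in place of quantile normalization these 4 lists had 0.0631 (immediate early and glucocorticoid), 0.135 (cardiomyocyte) and 0.273 (neuron).

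Hypoxia was also set against fragmentation, to compare the 2 exposures directly. Hnrnpll, a splicing regulator (0.68), Vamp3, a vesicle fusion protein (0.70), Gsta4, which detoxifies lipid aldehydes (0.61), Trak1 (0.86) and Cdh13, a receptor of adiponectin (1.03), were the higher genes with the smallest unadjusted p. Cga, the common chain of pituitary hormones (-0.66), Lefty1 (-0.68), Rhoc (-0.74), Rpl37a (-1.14) and Fam83g (-1.04) were the lower ones, and Vegfa differed by 0.40 ± 0.19 (adjusted p = 0.507) and Slc2a1 by 0.18 ± 0.23. In limma 0 probe sets passed, with 743 at an unadjusted p under 0.05 (smallest adjusted p 0.467), and no list passed (smallest 0.237).

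Within a tissue, with 1 array per condition and no replicates, some arrays carried transcripts far above their level on the other arrays of the tissue. On the muscle control array Fabp2 and Apoa1, lipid carriers made in the intestine, and Defa35 and Defa23, antimicrobial peptides of intestinal Paneth cells, stood above the fragmentation array, which differed from it by -5.09, -4.36, -4.71 and -3.45 log2. The muscle fragmentation array was higher by 4.87 for Adam7 and 4.31 for Gpx5, both secreted in the epididymis, and by 3.90 for Retn and 3.46 for Adipoq, hormones of adipocytes. The muscle hypoxia array was higher than control by 3.27 for Scd1 and 1.95 for Fasn, enzymes of fatty acid synthesis, by 2.42 for Adipoq and by 2.37 for Apoe, and lower for Apoa1 (-3.72), Snrpb (-3.70), Myh7 (-3.11) and Apoa4 (-2.77). Fatty acid and triglyceride synthesis genes had medians of 0.74 and 0.41 on the muscle fragmentation and hypoxia arrays, at the percentile 100 of random lists. On the same arrays adipocyte marker genes had medians of 0.71 (6 of 7 higher, percentile 99.85) and 0.48 (4 of 7, 99.35), and lipolysis genes of adipocytes 0.57 (percentile 100) and 0.13 (89.93). On the lung hypoxia array Acta1, the actin of skeletal muscle, was higher by 5.63, Myh1 by 4.53, Atp2a1, its calcium pump, by 3.53 and Tnnt3 by 3.48, and the skeletal muscle fibre list had a median of 1.15.

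**Figure D4:**
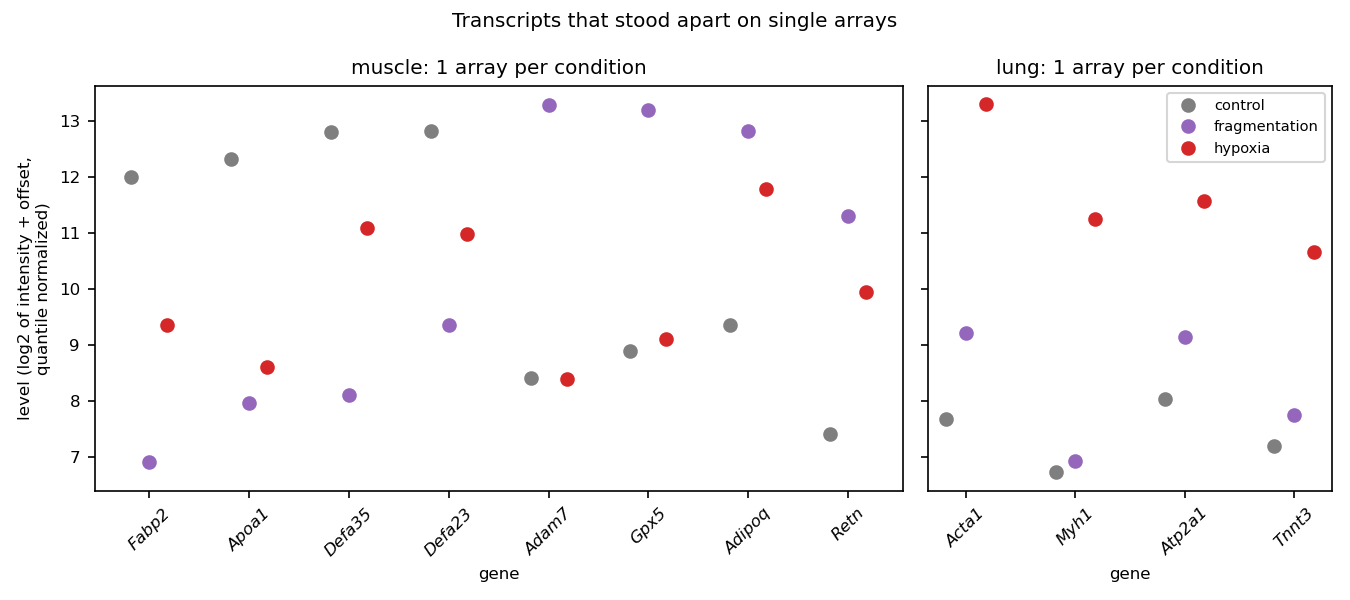
Log2 level of Fabp2, Apoa1, Defa35, Defa23, Adam7, Gpx5, Adipoq and Retn on the 3 muscle arrays and of Acta1, Myh1, Atp2a1 and Tnnt3 on the 3 lung arrays, 1 point per array. Fabp2 stands at 12.01 on the muscle control array and 6.91 on the fragmentation array, and Acta1 at 13.30 on the lung hypoxia array and 7.67 on the control array.

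In brain, Camk2a, a synaptic kinase, was higher than control by 2.95 with fragmentation and 3.19 with hypoxia, and Map2, a dendrite protein, by 2.49 and 2.32. Camk2a read 7.78 on the brain control array, near its mean of 7.83 in the other tissues. Its differences therefore cannot be taken as a change with either exposure. Map2 read 8.69 on that same array, and both of its differences rest on that reading. Gh, growth hormone, was higher by 2.83 with fragmentation, and Syt1, a synaptic calcium sensor, by 2.09 with hypoxia. Scgb1a1, the secretory protein of airway club cells, differed by -4.31 and -4.56, and Acta1 by -4.02 with fragmentation, both standing higher on the control array than on the other brain arrays. Atp6v0e2 (-4.74), Cplx1, a synaptic regulator (-4.36), and Epn1 (-4.25) were far lower on the brain hypoxia array. In heart, Rnf10 (3.39), Hba-a1, a haemoglobin chain (3.05), and Actc1, cardiac actin (2.85), were higher with fragmentation, and Fkbp8 (-2.93), Wbp4 (-2.37), Nkx2-5, a cardiac transcription factor (-2.01), and Hspg2, a matrix proteoglycan (-1.98), lower. With hypoxia Nomo1 (2.84), Nr1h3, a sterol receptor (2.70), Gpcpd1 (2.58) and Phf7 (2.28) were higher in heart, and Ift46 (-2.58), St8sia5 (-2.31), Abcg1, a cholesterol exporter (-2.21), and Sprr2b (-1.97) lower. In lung Scgb1a1 was higher by 4.42 with fragmentation, and Nppa, a natriuretic peptide, differed by -1.49 with fragmentation and -1.65 with hypoxia. Scgb1a1 read 8.69 on the lung control array, and its mean was 10.24 in lung against 10.16 in the other tissues. Actc1 read 10.43 on the heart control array, with a mean of 11.72 in heart against 12.21 in the others. Each read low in its own tissue, so neither difference can be taken as a change with fragmentation. Probe sets 2-fold or more from control numbered 298 with fragmentation and 457 with hypoxia in brain, 313 and 446 in heart, 126 and 219 in lung, and 590 and 517 in muscle.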

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

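The tests of the scaling, of the Con arrays numbered 1, of the s code, of muscle tissue in the lung sample, of a shared muscle gene response, and of probe saturation were chosen only after the result was seen.

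A difference between groups was found where the hypoxia effect of a gene list differed between Glucose and Con by the interaction contrast. The Actb ratio of 3' to 5' control probe sets was 1.70 and 1.37 on the Con hypoxia arrays and 0.756 to 1.27 on the other adipose arrays. Its part in these differences was not tested. Fatty acid and triglyceride synthesis genes had a more positive effect in Glucose (median 0.84, adjusted p = 4.02e-05, 13 of 15 genes; adjusted p = 0.241 with an estimated correlation). Skeletal muscle fibre genes did so too (median 2.27, adjusted p = 1.07e-06, 19 of 20), as did glycolysis genes (0.59, 0.00941, 12 of 14) and heat shock chaperones (0.43, 0.00778, 12 of 17), each with adjusted p = 0.988 with an estimated correlation. The glycolysis and muscle fibre lists share Pgam2 and Eno3, so they are not independent. Medians of the muscle fibre list differed within groups, with 0.49 and 1.80 on the Con non-hypoxia arrays. The muscle tissue held by each adipose sample is not given, and its part was not tested. Interferon response genes had a more negative effect in Glucose (median -0.49, adjusted p = 0.0231, 15 of 16; adjusted p = 0.988 with an estimated correlation). Fatty acid and triglyceride synthesis passed with each of the 8 arrays left out in turn. Skeletal muscle fibre was lost without the Glucose non-hypoxia array numbered 1 (0.215), on which the list's median stood at -2.80 against the mean of the 8 arrays. Glycolysis was lost without the Con non-hypoxia array numbered 1 (0.209), the Con hypoxia array numbered 2 (0.327), the Glucose hypoxia array numbered 2 (0.0963) or the Glucose non-hypoxia array numbered 1 (0.448). Heat shock chaperones were lost without the first 2 of these (0.713 and 0.141) or the last (0.0856). Interferon response was lost without the first 2 (0.235 and 0.118), the Glucose hypoxia array numbered 1 (0.292) or the Glucose non-hypoxia array numbered 2 (0.207).

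Lymphocyte genes were lower on the Glucose adipose arrays: 13 of 14 B cell and T cell genes, with a median log2 difference of -1.88. Quantile normalization left the median at -1.879 and leaving out the Con arrays numbered 1 left it at -2.167, which argues against the scaling and those arrays as the whole cause. The median was -2.087 within s2 and -1.577 within s4. Every group holds 1 array of each code, so by design an equal shift between the codes could not make the difference, and these values add no test of it. Lymph node tissue in the Con pieces may be a source: of 9 lymph node genes fixed before their values were read, Cxcl13 (-3.30), Cxcr5 (-1.36) and Ccr7 (-1.15) were lower and Madcam1 (0.77), Chst2 (0.41) and Fut7 (0.31) were not, with a median of -0.0746 over the 7 above the floor. That median met the bound set beforehand for counting it out, but only 1 of the 7, Cxcl13, was bright enough on Con to fall by 1.88 above the floor, a condition added after the value was seen, so lymph node tissue and a difference in the lymphocytes of the fat itself cannot be told apart. Glycam1, the ligand made by lymph node vessels, was at least 14.2-fold lower on Glucose. It was singled out after its value was seen, so it does not decide between them. A difference between the mice or treatments behind the titles Con and Glucose stays open and was not tested, since the labels do not say what they stand for.

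Genes of other tissues stood high on single arrays of the panel: Fabp2, Defa35 and Apoa1 on muscle control, Adam7 and Gpx5 on muscle fragmentation, and Acta1 and Myh1 on lung hypoxia. Intestinal tissue in the muscle control sample could account for the first set, and 23 further intestine genes had a median difference of 0.479 from the other muscle arrays, with 8 of them 2-fold or more higher (Vil1 2.47), a value between the bounds set beforehand. Epididymal tissue in the muscle fragmentation sample gave 0.691 over 7 further genes (Cuzd1 2.40, Lcn5 1.36), between the bounds as well, so both stay open. Skeletal muscle tissue in the lung hypoxia sample also stays open, with 55% of the muscle fibre genes (11 of 20) 2-fold or more higher. A muscle gene response to hypoxia shared with heart was argued against by a median of 0.0701 in heart. The median of -0.358 in brain decides nothing, since the brain control array itself had a muscle fibre median of 0.831 over the other brain arrays. No biological explanation was tested within 1 array per condition.

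Bright transcripts such as Atp6v0e2, Cplx1 and Epn1 were far lower on the brain hypoxia array than on the control array. Of 61 probe sets 4-fold or more lower there, 65.57% (40) lay among the brightest 20%, against 30% (3 of 10) in heart, 0% (0 of 1) in lung and 10% (3 of 30) in muscle with hypoxia and 37.04% (10 of 27) in muscle with fragmentation. Probe saturation on this array, which has the higher deposited intensity, may be a source and stays open, since that share restates how the pattern was noticed and its bounds were written afterwards. Arrays of usual intensity had low readings too. The 3' control probe set of Gapdh read 70.4 on muscle hypoxia and 207 on muscle control, against 7825 and 7926 at the 5' end. That of Actb read 228 on lung control, against 7927. Bright transcripts may thus read low on other panel arrays as well. Quantile normalization was argued against, since 37 of the 40 stayed 4-fold or more lower after rescaling alone. A hypoxia response shared by the tissues was argued against by the medians of the 40 in heart (-0.0929), lung (-0.213) and muscle (-0.160), where 37, 38 and 38 of them were bright enough on the control array to fall 4-fold, while one in brain alone stays open and was not tested.

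Whether chance can be excluded was asked with other groupings of the same arrays. In a refit with 2 groups, Glucose against Con gave 839 probe sets and the highest of the other splits gave 4 (1 of 35 splits as large as the real one), so chance can be excluded if the 8 arrays vary independently. Same-numbered arrays of Con or of Glucose went together, and only 3 splits keep those together (highest other 4), too few for a share under 0.05. For counts of 0 the groupings decide nothing, since each gives at least as many. This holds for average hypoxia in adipose tissue (0 in limma, 110 at an unadjusted p under 0.05 in the fit of 4 groups, 35 of 35 splits, highest other the 839 of the Glucose and Con split). It holds as well for hypoxia, fragmentation and their difference across the tissues (0 each in limma, 371, 336 and 743 at an unadjusted p under 0.05, 100 of 100 groupings, highest other 1). Chance can be excluded for tissue identity, with 1 of 100 groupings as large each time: brain 3683 (highest other 2792), heart 2862 (1290), lung 4604 (3714) and muscle 3901 (2064). Some of those groupings kept a tissue's 3 arrays together, and where its arrays were parted the highest was 200 for brain, 1290 for heart, 310 for lung and 2064 for muscle.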

How the results depend on the processing

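The tests without both Con arrays numbered 1, within s2 or s4, with the nested block, with the panel rescaled, and without the brain hypoxia or the muscle control array were chosen after seeing the data, as were list tests with arrays or tissues left out or with another scaling. The other settings were planned. Counts and lists stayed within 1.5 times their value in 240 of the comparisons with an alternative and moved further in 91. Values of named genes kept direction and side of the threshold in 2452, lost the threshold in 50 and turned in 43, and those of single arrays, which have no test, kept their sign but moved by over 1.5 times in 46. Many of the 2452 are genes that passed in neither setting. These tallies therefore do not measure how stable the calls were. For Glucose minus Con, an offset 4 times larger lost Cidea (adjusted p = 0.0854 in limma), Tnnt1 (0.127), Pigs (0.116) and Map6 (0.0643). The smaller offset lost Pigs (0.0581). No filter lost Cidea (0.141), Tnnt1 (0.107), Pigs (0.0988) and D430019H16Rik (0.0518). Where a value moved or turned the cause was not tested, except that fewer arrays or probe sets were tested where arrays were left out or the filter was raised.

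For Glucose minus Con in adipose tissue (565 probe sets), quantile normalization gave 575 (546 shared), an offset 4 times smaller 409 (402 shared), one 4 times larger 566 (384 shared, 61.1% of them higher), no filter 381 and the 60th percentile filter 427. Trend and robust options gave 650, array weights 557 and the s code as a term 474 (450 shared). It was 92 without both Con arrays numbered 1 (89 shared), 0 within s2 in limma (1189 at an unadjusted p under 0.05) and 142 within s4 (107 shared). With 1 array left out, the lone array of its group being assumed to vary like the others, it ranged from 240 (Glucose hypoxia number 1) to 459 (Glucose non-hypoxia number 2). The share of calls higher on Glucose ran from 39.2% to 52.9% in these and was 29.3% without both Con arrays numbered 1. The count was 267 without Glucose hypoxia number 2, 325 without Glucose non-hypoxia number 1, 344 and 362 without Con hypoxia numbers 1 and 2, and 361 and 347 without Con non-hypoxia numbers 1 and 2.

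The labels give same-numbered arrays no shared source, and the reported fit does not pair them. After removing group means, same-numbered arrays correlated at 0.181 within Con, 0.415 within Glucose and -0.046 to -0.137 across, so the numbers go together within Con and within Glucose and not between them. With the replicate number as a block, 466 probe sets passed for Glucose minus Con (440 shared), and 0 for the hypoxia contrasts in limma with 131, 238, 181 and 270 at an unadjusted p under 0.05 (average, within Con, within Glucose, difference). A block nested in Con and Glucose gave 723 (515 shared). It removes the spread between the numbers within Con and within Glucose. If same-numbered arrays share a source, that spread is the one Glucose minus Con should be tested on, so the higher count adds no support.

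Without the filter, a few probe sets near the floor passed in the hypoxia contrasts, named here though chosen after their values were seen. There were 4 for the average (Gli3 0.43, Strada -1.07, Kcnj9 -0.62, Bcar1 -0.77), 2 within Con (Gli3 0.86, Strada -1.08), 4 within Glucose (Strada -1.06, Tsn 0.21, Kcnj9 -1.24, Bcar1 -1.54) and 3 for the difference (Gli3 -0.86, Kcnj9 -1.24, Bcar1 -1.54). In the other settings run these contrasts gave 0 in limma, with 110 to 246 at an unadjusted p under 0.05 in the reported fits.

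The genes fixed in advance, none of which passed, turned in sign as follows. Quantile normalization gave Adipoq 0.064 for Glucose minus Con and -0.0046 for average hypoxia. An offset 4 times larger gave Slc2a1 0.40 within Con and -0.28 for the difference. Within s2, Adipoq was 0.28 for Glucose minus Con and -0.23 for average hypoxia, Slc2a1 0.71 and -0.29, Lep 1.27 for Glucose minus Con and Vegfa -0.41 for average hypoxia. Without both Con arrays numbered 1, Adipoq was 0.33 for the difference, -0.43 within Con and -0.27 on average, and Slc2a1 0.50 for Glucose minus Con and -0.0016 for average hypoxia.

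With 1 adipose array left out, Slc2a1 ranged from -1.04 to 0.37 for Glucose minus Con, from -1.56 to 1.25 within Con and from -0.13 to 1.27 for average hypoxia. Adipoq ranged from -0.23 to 0.81 within Con, -0.75 to 0.54 within Glucose, -0.23 to 0.42 on average and -1.04 to 0.25 for the difference. Vegfa ranged from -0.44 to 1.01 within Con, -0.77 to 0.26 within Glucose, -0.35 to 0.38 on average and -1.27 to 0.18 for the difference. Lep ranged from -1.40 to 0.56 for Glucose minus Con, -1.78 to 2.13 within Glucose, -0.34 to 1.61 on average and -2.88 to 1.02 for the difference. With 1 tissue left out, Slc2a1 ranged from -0.0014 to 0.42 for hypoxia and from -0.085 to 0.18 for fragmentation.

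Of the gene lists, 9 passed for Glucose minus Con, 5 for hypoxia within Con, 3 within Glucose, 5 for the difference, 4 for hypoxia and 1 for fragmentation across the tissues. With an estimated correlation 0 passed in each of these, and with fry 4 (1 up, 3 down) for Glucose minus Con and 0 in the others. With the mean of a gene's probe sets, 1 passed for average hypoxia and 2 for fragmentation. Without both Con arrays numbered 1, 5 passed for Glucose minus Con (1 up, 4 down) and 4 for average hypoxia (1 up, 3 down). With 1 array or tissue left out the number of lists ranged from 0 to 8 for average hypoxia, 1 to 12 within Con, 0 to 11 within Glucose, 2 to 10 for the difference, 2 to 4 for hypoxia, 2 to 4 for fragmentation and 0 to 5 for hypoxia minus fragmentation. The panel as deposited gave 7 for fragmentation (6 up, 1 down) and 5 for hypoxia minus fragmentation, the panel rescaled gave 2 for fragmentation and 0 for hypoxia, and leaving out the brain hypoxia array gave 2 for fragmentation.

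In the panel under the deposited scaling, which shifted the median of all probe sets by 0.41 for hypoxia minus control and by 0.55 for brain identity, 1 probe set passed for hypoxia (Nomo1 1.88) and 5 for hypoxia minus fragmentation (Rpl41 -1.81, Acta1 2.51, Tnnt3 1.96, Pvalb -1.75, Myh4 1.74), chosen after their values were seen. Tissue identity gave 1071 for heart, 2632 for lung and 1771 for muscle, and 6715 probe sets were 2-fold or more apart between brain hypoxia and control, 6676 of them higher. With 1 condition left out, heart identity ranged from 1713 (without fragmentation) to 2486 (without hypoxia), with 1763 without control.

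The counts of probe sets 2-fold or more from control within a tissue moved with the offset and the filter, in the order brain, heart, lung and muscle, fragmentation before hypoxia in each. An offset 4 times larger gave 113, 233, 96, 129, 34, 74, 232 and 157, and no filter gave 520, 720, 623, 783, 293, 414, 1073 and 1107. The 60th percentile filter gave 191 for brain fragmentation, 162 and 237 for heart, 62 and 136 for lung and 333 and 279 for muscle. An offset 4 times smaller gave 220 for lung fragmentation. Signal over background limits the adipose values, as up to 21.2% of an array's values lay at or below 0 and transcripts under the floor cannot be seen to fall.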

Other observations

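No test in this part was chosen only after the result was seen, but the gene groups described were picked for their values.

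Further genes of metabolism and signalling passed in limma between the Glucose and Con adipose arrays while their lists did not. Ccn1 (2.42) and Ccn2 (2.50), matrix-associated signalling proteins, and Klf6, a zinc finger factor (1.19), rose among the 20 immediate early genes, whose list had adjusted p = 0.0877. Elovl6, a fatty acid elongase, fell (-2.64) and Me1, which makes NADPH for lipid synthesis, rose (0.97), in a list with adjusted p = 0.522. Pck1, the enzyme that feeds glycerol synthesis in fat, fell (-1.45). Gpx3, a secreted glutathione peroxidase, fell 3.99-fold and Gclm, a subunit of the enzyme that makes glutathione, rose (1.02). Nfil3, a clock factor, rose by 1.16, Cdkn1a, a cell cycle inhibitor, by 1.81 and Itgax, an integrin of macrophages and dendritic cells, by 1.52. Genes of endothelial cells, erythroid cells and insulin signalling had 0 members past the threshold in limma, with list adjusted p of 0.687, 0.646 and 0.687.

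Within single tissues other gene groups stood at the edge of random lists, with 1 array per condition and no test. Extracellular matrix genes had a median of -0.41 in heart with fragmentation, with 22 of 29 lower. In lung with hypoxia, glycolysis genes had a median of 0.43 (14 of 16 higher), glucocorticoid response genes 0.35 and respiratory chain genes 0.16 (41 of 50 higher), on the array that also carried skeletal muscle transcripts. In muscle, adipokine genes had medians of 0.61 with fragmentation and 0.61 with hypoxia, on arrays where adipocyte marker genes had medians of 0.71 and 0.48 (percentiles 99.85 and 99.35). There, neuron genes had a median of 0.61 with hypoxia (9 of 12 higher).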
